A study of Mus musculus with 8 samples.

How the data were processed

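Keratinocytes of wild-type and Nfkbiz knockout mice of the C57BL/6 strain were compared 3 days after transduction with the v-rasHa oncogene, with 4 biological replicates per genotype as the labels state. Per the labels' protocols, cells were kept in regular medium, total RNA was isolated with Trizol and a Qiagen column and labelled with biotin, which is the labelling of a one-colour oligonucleotide array. The deposited table held 1 value per probe set and array for 11373 probe sets. The authors' deposited values were taken as log2 signals from their range of 1.57 to 13.9, and the summarisation method, the normalization and the genome build are not given in the sources used here. Array medians lay within 4.49 to 4.57, so the arrays were on a similar scale as deposited. Neither scan dates nor batches were given in the sources used here, and no detection calls were used, so low signals could not be told from background.

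Probe sets were named through the annotation of the platform. Of the 11373 probe sets, 9374 had 1 gene symbol, 479 had several and 1520 had none in that table. Genes were represented by the probe set with 1 symbol and the highest mean over the 8 arrays, which gave 9294 genes. A reference gene table of the assembly GRCm38.p6 matched 9201 of these by Entrez identifier and was used for older symbols and for the order of genes only. Some symbols of the platform are older names: Il1f6, Il1f8 and Il1f9 are now Il36a, Il36b and Il36g. Nfkbiz, Hras and Cxcl1 were not among the genes analysed here, and Krt14 was represented only by a probe set that also names Krt17, so these were not analysed, and the planned check of the knockout with its alternatives could not be run. Probe sets with an _x_at or _s_at suffix can bind several transcripts. They represented 158 genes with _s_at and 91 with _x_at, among them S100a8 and Lce3b.

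Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on the deposited log2 values, with no covariate, and log2 fold changes are knockout minus wild-type with their moderated standard errors. Adjusted p-values are Benjamini-Hochberg over the 9294 genes, with a threshold of 0.05, and a gene is said to have risen, fallen or been called where it passed. P-values measure the spread between the biological replicates of each genotype. Gene lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the 19 lists with at least 5 measured members, with the estimated correlation and with fry as alternatives. Fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. Of the 9 lists that passed, 4 also passed with an estimated correlation: cytokines and chemokines, antimicrobial genes, interferon-stimulated genes, and glycolysis and hypoxia. The 20 lists, the test, the alternatives and the rule for naming genes were fixed before the data were examined. Many listed symbols, some of them older names of the same gene, were not measured. The measured members were 12 of 47 symbols for cell cycle, 10 of 33 for glycolysis and hypoxia, 5 of 22 for interleukin-1 receptor signalling and 19 of 28 for cytokines and chemokines. Results of a list describe its measured members only. Apart from Lyz2, which is in the antimicrobial and leukocyte lists, no measured gene was in more than 1 list. Genes named are the 12 largest falls and 12 largest rises among called genes whose groups do not overlap, up to 4 called members of each list with the largest change, and Il1a, Cxcl2, Lcn2, Krt1 and Krt10 in any case, which gave 75 genes. A further 55 genes were chosen after their values were seen: Tnf, Il23a, Il1f8, Il1f9, S100a9, Defb3, Defb4, Defb6, Rela, Tnip1, Dusp5, Dusp6, Myc, Krt19, Krt16, Mmp10, Gm6958, Tfg, Filip1l, Stfa3, Stfa2l1, Csta1, Bex3, Bex4, Irgm1, Irgm2, Gjb2, Gjb6, Flg, Oas2, Oas1a, Oas3, Mx2, Il1b, Olfml3, Rcn3, Srpx2, Efemp1, Xdh, Padi1, Anxa9, Arg1, Serpinb9b, Serpinb7, Serpinb6c, Pdpn, Dct, Hoxa10, Hoxb6, Lce1g, Lce1h, Lce1i, Gbp3, Cd68 and Igtp.

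The same functions were tested on simulated data: in 20 runs, 200 of 9294 genes were changed by known folds with the spread of the real arrays. Of the changed genes, 39.3% were recovered at 1.2-fold, 93.7% at 1.5-fold, 99.6% at 2-fold and 100% at 3-fold, and 4.77% of calls were false. A planted list with a shift of 0.3 was recovered in 20 of 20 runs, and none of 360 unchanged lists was called by camera. Genes were simulated as independent of each other. The simulation therefore does not show how often camera calls unchanged lists whose members vary together. In the real arrays, the estimated correlation was 0.62 in the differentiation list. The number of arrays limits the precision. The difference between arrays of the same genotype had a standard deviation of 0.157 to 0.175 across probe sets, so no array was a duplicate of another.

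Alternatives were repeated quantile normalization, centring on array medians, leaving out the lowest 25% of genes, the mean of a gene's probe sets, the replicate number as a block, eBayes with trend and robust settings, array weights, leaving out each array in turn, stricter thresholds of adjusted p 0.01 and 1.5-fold, and treat against 1.2-fold. Probe sets with _x_at or _s_at suffixes left out, and genes under a log2 signal of 5 left out, were added after seeing the data. An alternative pseudocount did not apply because the values were already logarithmic. Testing all 11373 probe sets gave 863 past the threshold, 455 higher and 408 lower. Single p-values of list means come from two-sided exact permutation tests, and intervals over genes from 10000 bootstrap resamples.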

Results

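Gene expression was measured on 8 one-colour oligonucleotide arrays hybridised with biotin-labelled total RNA from mouse keratinocytes of the C57BL/6 strain. All cultures had been transduced 3 days earlier with the v-rasHa oncogene, an activated viral form of Hras that is carried into keratinocytes by a retrovirus. The 4 wild-type RAS arrays came from wild-type cells, and the 4 knockout RAS arrays came from cells lacking Nfkbiz, which encodes IkBz, a nuclear regulator of NF-kB target genes. Per the labels, the 4 samples of each genotype were biological replicates. The table held log2 signals of 11373 probe sets, of which 9294 genes were tested, and array medians lay between 4.49 and 4.57 on the log2 scale. With 4 arrays per group, the median standard error of a log2 fold change was 0.069. Correlations across probe sets were 0.997 to 0.998 between arrays of the same genotype and 0.994 to 0.996 between genotypes, and probe sets are not independent replicates. The first principal component held 49.7% of the variance, with scores of -10.4 to -8.62 in wild-type arrays and 8.71 to 10.8 in knockout arrays.

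The only comparison of the design asks which transcripts differ between knockout and wild-type keratinocytes that all carry v-rasHa. No culture without the oncogene was measured. The differences can therefore not be assigned to a program of oncogenic RAS, or told from differences present without it. Transcripts of cytokines, of antimicrobial genes and of glycolysis and hypoxia genes were lower in the knockout cells as groups, and those of interferon-stimulated genes were higher. Terminal differentiation genes were lower too, but that list had an adjusted p = 0.254 with an estimated correlation. Lcn2, which encodes the siderophore-binding protein lipocalin-2, fell the most, from a log2 signal of 6.74 ± 0.22 to 3.18 ± 0.24 (SD, n = 4 per group), an 11.8-fold difference in signal. The knockout mean of Lcn2 and 3 of its 4 values lay below the lower quartiles of the arrays (3.33 to 3.39), where signal could not be told from background, so this fold describes signals only. Ubd, which encodes a ubiquitin-like protein inducible by cytokines, rose the most, from 5.30 ± 0.27 to 7.92 ± 0.25 (SD, n = 4 per group), a 6.15-fold difference. In limma with Benjamini-Hochberg adjustment, 827 of the 9294 genes passed an adjusted p of 0.05, 415 higher and 412 lower in the knockout. With each array centred on its median, 796 genes passed, 482 higher and 314 lower, so the balance between directions depended on the centring. Most changes were small: the median size of a called log2 fold change was 0.35, and 34 genes fell and 16 rose by at least 2-fold. Over all 9294 genes, the values of the 2 groups did not overlap for 1476 (15.9%), where chance alone separates 2.86% for 4 against 4. Nfkbiz, Hras and Cxcl1 were not analysed here, so the knockout itself was not checked from these values.

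**Figure D1:**
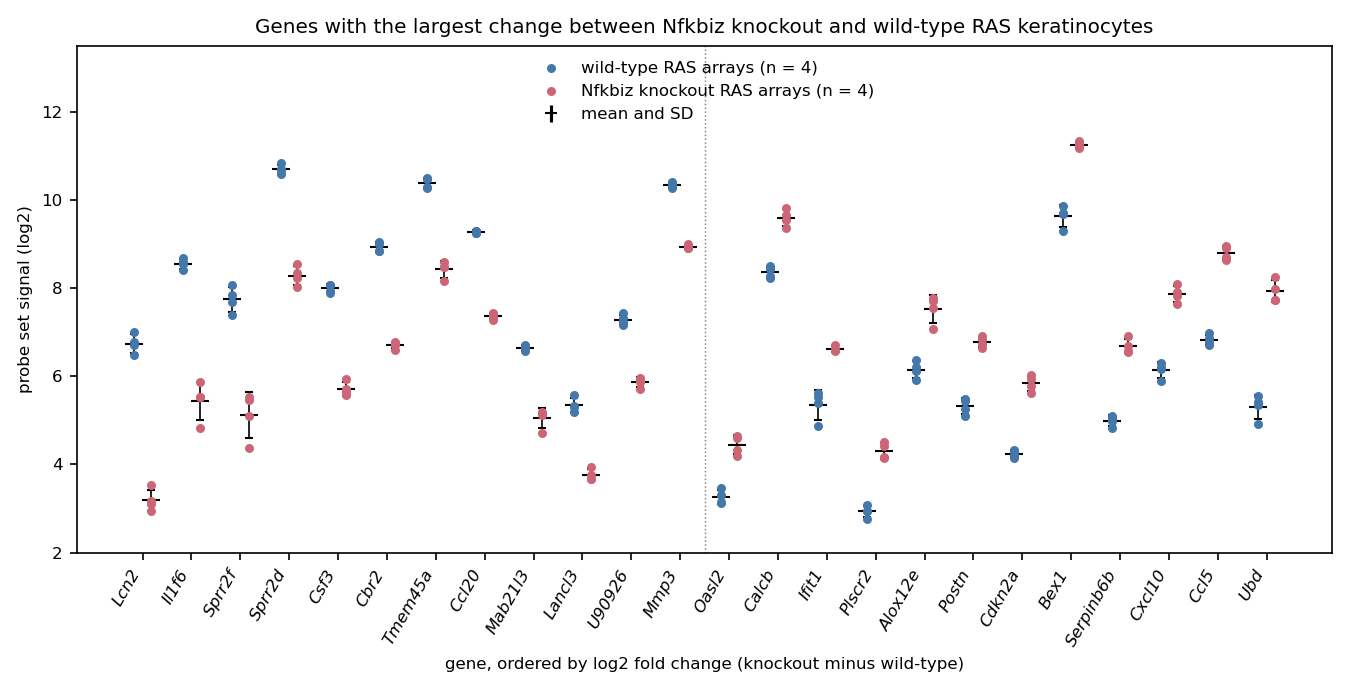
Probe set signals on the log2 scale for the 12 genes with the largest fall and the 12 with the largest rise among called genes, ordered by log2 fold change. Points are single arrays (4 wild-type and 4 knockout RAS arrays) and bars are the mean and SD. Lcn2 lies at the left end with a log2 fold change of -3.56 and Ubd at the right end with 2.62.

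Cytokine and chemokine transcripts fell as a group in the knockout keratinocytes. Of 19 measured members, 13 fell, 2 rose and 4 did not pass the test, with a median log2 fold change of -0.56 (camera adjusted p = 1.85e-13). The largest falls were in Il1f6, the gene of the epithelial cytokine IL-36 alpha, with a log2 fold change of -3.11 ± 0.17 (SE), and Csf3, the gene of granulocyte colony-stimulating factor, with -2.27 ± 0.08. Ccl20, a chemokine for CCR6-bearing lymphocytes, fell by 1.91 ± 0.05 and Csf2, the gene of granulocyte-macrophage colony-stimulating factor, by 1.35 ± 0.09. Il1a, the epidermal interleukin-1, fell from 10.48 ± 0.06 to 9.58 ± 0.07 (SD, n = 4 per group; limma adjusted p = 2.12e-06), and the neutrophil chemokine gene Cxcl2 fell by 0.56 ± 0.08 (limma adjusted p = 0.000624). The other IL-36 genes, Il1f8 and Il1f9, named after their values were seen, fell by 0.54 and 0.49. The 2 members that rose, also named after their values were seen, were Il23a with 0.42 ± 0.07 and Tnf with 0.27 ± 0.05. Il1b, chosen in the same way, had a log2 fold change of -0.14 and an adjusted p of 0.226. Adjusted over the list alone, 15 members fell and 3 rose, and the list passed with an estimated correlation (adjusted p = 0.00828). Fibroblast markers, described among the other cell types, were lower in the same arrays with a median of -0.50 (camera adjusted p = 0.1345 with an estimated correlation). This median is repeated beside other lists as context only, and its bearing on them was not tested.

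Antimicrobial and acute-phase genes fell too. Of 17 measured members, 10 fell, none rose and 7 did not pass the limma test, and the median log2 fold change was -0.42 (camera adjusted p = 6.37e-11, and 0.00744 with an estimated correlation). After Lcn2 came the chitinase-like gene Chil1 with -1.13 ± 0.06 (SE), S100a8 with -1.03 ± 0.05 and the protease inhibitor gene Slpi with -0.94 ± 0.06. S100a9, whose protein pairs with that of S100a8 as calprotectin and which was named after its values were seen, fell by 0.85 ± 0.07. Adjusted over the list alone, 10 members fell and none rose, and the median of fibroblast markers in these arrays was -0.50. The median signal of the list was 5.03, close to the array medians, and its median log2 fold change was -0.83 with genes under a log2 signal of 5 left out, an alternative chosen after seeing the data.

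Cornified envelope and other terminal differentiation genes were lower, while Krt1 and Krt10 did not pass the test. Of 27 measured members, 12 fell, none rose and 15 did not pass the test, with a median log2 fold change of -0.30. The camera test gave an adjusted p of 1.54e-09, but the adjusted p = 0.254 with an estimated correlation, which was 0.62 between members. Sprr2d, a small proline-rich precursor of the cornified envelope, fell from 10.70 ± 0.10 to 8.28 ± 0.21 (SD, n = 4 per group), and its relative Sprr2f, outside the list, fell by 2.63 ± 0.23 (SE). The late cornified envelope genes Lce3a and Lce3b had log2 fold changes of -1.21 ± 0.12 and -0.82 ± 0.12, and Alox12b, a lipoxygenase of the skin barrier, had -0.78 ± 0.13. The knockout mean of Alox12b, 4.42, lay below the array medians. Krt1 and Krt10, the keratins of the early spinous layer, had log2 fold changes of 0.00 ± 0.10 and 0.12 ± 0.08 (limma adjusted p = 0.996 and 0.419), and Flg, the filaggrin gene, named after its values were seen, had 0.27 ± 0.13 (adjusted p = 0.252). In limma 16 members fell and none rose adjusted over the list alone. Fibroblast markers had a median of -0.50 in the same arrays, and their bearing on this list was not tested. Sprr2 and Lce3 are families of related genes whose probe sets may share targets, so values of single members are uncertain.

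Interferon-stimulated genes rose in the knockout cells. Of 21 measured members, 14 rose, none fell and 7 did not pass the limma test, with a median log2 fold change of 0.48 (camera adjusted p = 4.80e-20, and 0.00744 with an estimated correlation). The chemokine gene Ccl5 rose from 6.83 ± 0.11 to 8.80 ± 0.16 and Cxcl10 from 6.14 ± 0.18 to 7.86 ± 0.19 (SD, n = 4 per group). The antiviral gene Ifit1 rose by 1.27 ± 0.14 (SE) and Oasl2, a relative of the oligoadenylate synthetases, by 1.19 ± 0.11, although the Oasl2 mean of 4.44 in the knockout lay below the array medians. Other antiviral genes of the list, named after their values were seen, did not pass the test: Oas1a, Oas2, Oas3 and Mx2 had log2 fold changes of 0.01, 0.00, 0.02 and 0.06, with adjusted p of 0.963, 0.989, 0.934 and 0.789. Adjusted over the list alone, 17 members rose and none fell, while fibroblast markers in the same arrays had a median of -0.50.

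Genes of the NF-kB pathway itself were more often higher than lower. Of 10 measured members, 5 rose, 1 fell and 4 did not pass the test, with a median log2 fold change of 0.18 (camera adjusted p = 0.0051, but adjusted p = 0.254 with an estimated correlation). Relb, a subunit of NF-kB, rose by 0.64 ± 0.09 (SE), the adhesion molecule gene Icam1 by 0.56 ± 0.06 and Nfkbid, a nuclear relative of Nfkbiz, by 0.46 ± 0.09. Rela and Tnip1, named after their values were seen, rose by 0.23 and 0.24, and the kinase gene Ikbke fell by 0.25 ± 0.06. The list had an adjusted p of 0.0511 with genes under a log2 signal of 5 left out, an alternative chosen after seeing the data. A total of 6 members rose and 2 fell adjusted over the list alone, in arrays with fibroblast markers at a median of -0.50. Without wild-type RAS replicate 2, or without knockout RAS replicate 1, 3 members rose in place of 5, with list medians of 0.160 and 0.163. Among 5 measured components of interleukin-1 receptor signalling, Sigirr, an inhibitory receptor, rose by 0.32 ± 0.07, the decoy receptor gene Il1r2 fell by 0.27 ± 0.06 and 3 did not pass the test. Il1r2 lay at 4.56 in wild-type and 4.29 in knockout arrays, near or below the array medians. Of the 5 components, 1 rose and 3 fell adjusted over the list alone, and the list did not pass (camera adjusted p = 0.36).

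Output genes of RAS and MAP kinase signalling were slightly lower in the knockout. Of 13 measured members, 5 fell, none rose and 8 did not pass the limma test, with a median log2 fold change of -0.12 (camera adjusted p = 0.00997, but adjusted p = 0.254 with an estimated correlation). The immediate early gene Fos fell by 0.54 ± 0.06 (SE), Phlda1 by 0.40 ± 0.07, the EGF receptor ligand gene Epgn by 0.37 ± 0.07 and Egr1 by 0.29 ± 0.08. Dusp5, named after its values were seen, fell by 0.20 ± 0.05. The ERK phosphatase gene Dusp6 and Myc, chosen in the same way, had log2 fold changes of 0.14 and 0.01 with adjusted p of 0.162 and 0.931. When adjusted over the list alone, 6 members fell and 1 rose, with fibroblast markers at a median of -0.50. The calls of Egr1 and Dusp5 were lost in several alternatives, where their adjusted p reached 0.119 and 0.117. In place of 5, 3 members fell with arrays centred on their median, and also without any single array other than wild-type RAS replicate 1. The list median lay between -0.1609 and -0.0811 in these runs.

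Keratins split in direction. Of 6 measured stress and simple-epithelial keratins, 3 rose and 3 fell, also when adjusted over the list alone. Krt7 and Krt18, keratins of simple epithelia, rose by 0.76 ± 0.05 and 0.68 ± 0.06 (SE), and Krt19, named after its values were seen, by 0.54 ± 0.09. Krt6b, a keratin of activated epidermis, fell from 12.01 ± 0.11 to 10.63 ± 0.25 (SD, n = 4 per group), the hair follicle keratin Krt75 fell by 0.95 ± 0.10, and Krt16, named after its values were seen, fell by 0.27 ± 0.06. The list did not pass (camera adjusted p = 0.66), and its median of 0.14 and its mean of -0.10 differ in sign. Of 10 basal keratinocyte and adhesion genes, the hemidesmosome collagen gene Col17a1 fell by 0.31 ± 0.07 and 9 did not pass the test, with the same counts adjusted over the list alone (camera adjusted p = 0.66).

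Cell cycle genes were slightly higher in the knockout. Of 12 measured members, 7 rose, none fell and 5 did not pass the limma test, with a median log2 fold change of 0.20 (camera adjusted p = 9.56e-05, but adjusted p = 0.178 with an estimated correlation). The mitotic kinesin gene Kif20a rose by 0.39 ± 0.06 (SE), the proliferation marker Mki67 by 0.33 ± 0.06, Plk1 by 0.24 ± 0.06 and Ccnb2 by 0.23 ± 0.05. When adjusted over the list alone, 8 members rose and none fell by limma, against a median of -0.50 for fibroblast markers. In place of 7, 3 members rose without wild-type RAS replicate 1 or 2 or knockout RAS replicate 2 or 4, and 4 rose without wild-type RAS replicate 4 or knockout RAS replicate 3. The list median lay between 0.174 and 0.217 in these runs. Cdkn2a, the gene of the cell cycle inhibitors p16 and p19ARF, rose from 4.25 ± 0.08 to 5.84 ± 0.17 (SD, n = 4 per group). The wild-type mean of Cdkn2a lay below the array medians. The neighbouring gene Cdkn2b rose by 0.65 ± 0.06. In the senescence and p53 target list of 12, Cdkn2a and Cdkn2b were the 2 genes that rose, Plk3 fell by 0.22 ± 0.06 and 9 did not pass. Adjusted over the list alone, 3 rose and 1 fell. That list did not pass (camera adjusted p = 0.0701), although without knockout RAS replicate 1 its adjusted p was 0.0302.

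The matrix remodelling and wound response list did not pass as a group. Of its 14 measured members, 3 fell, 2 rose and 9 did not pass the test, with a median log2 fold change of -0.07 (camera adjusted p = 0.264). Mmp3, the stromelysin-1 gene, fell from 10.34 ± 0.06 to 8.94 ± 0.05 (SD, n = 4 per group), the collagenase gene Mmp13 fell by 0.80 ± 0.07 (SE), and Mmp10, named after its values were seen, fell by 0.56 ± 0.06. Ccn2, the gene of connective tissue growth factor, rose by 0.86 ± 0.05, and Adamts1 rose by 0.68 ± 0.06. Adjusted over the list alone, 5 members fell and 3 rose, and 5 fell with genes under a log2 signal of 5 left out. Mmp3 is also made by fibroblasts, whose markers had a median of -0.50 in this comparison.

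Glycolysis and hypoxia genes fell together. Of 10 measured members, 7 fell, none rose and 3 did not pass the limma test, with a median log2 fold change of -0.29 (camera adjusted p = 6.58e-08, and 0.00744 with an estimated correlation). Bnip3, a mitophagy gene induced by low oxygen, fell by 0.75 ± 0.08 (SE), the lactate transporter gene Slc16a3 by 0.60 ± 0.12, the collagen prolyl hydroxylase gene P4ha2 by 0.54 ± 0.06 and hexokinase gene Hk2 by 0.44 ± 0.06. Adjusted over the list alone, 8 members fell and none rose, in arrays where fibroblast markers were lower with a median of -0.50. Among 7 sterol biosynthesis genes, Nsdhl rose by 0.80 ± 0.06 and Tm7sf2 by 0.26 ± 0.07, with the same counts adjusted over the list alone (camera adjusted p = 0.204), and the median of -0.02 and the mean of 0.13 differ in sign. The call of Tm7sf2 was lost without any single array other than wild-type RAS replicate 3 and knockout RAS replicate 2. Of 13 oxidative stress genes, the glutathione peroxidase gene Gpx2 fell by 0.55 ± 0.07 and 12 did not pass, also adjusted over the list alone (camera adjusted p = 0.364). Of 7 unfolded protein and heat-shock genes, Atf3 rose by 0.66 ± 0.07, Chac1 and Sdf2l1 fell by 0.34 ± 0.06 and 0.24 ± 0.05, and 4 did not pass, while adjusted over the list alone 1 rose and 3 fell (camera adjusted p = 0.36). Sdf2l1 lost its call without wild-type RAS replicate 1 or 2 or knockout RAS replicate 1.

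Markers of other cells that a keratinocyte culture can hold were measured in the same arrays. Of 9 fibroblast markers, 7 fell, 1 rose and 1 did not pass the test, with a median log2 fold change of -0.50 (camera adjusted p = 1.27e-05, and adjusted p = 0.1345 with an estimated correlation). Twist2 fell from 8.51 ± 0.04 to 7.49 ± 0.12 (SD, n = 4 per group), the proteoglycan gene Dcn fell by 0.97 ± 0.08 (SE) and Dpt by 0.85 ± 0.07, but Postn, the periostin gene, rose by 1.47 ± 0.09. The counts were the same adjusted over the list alone. Of 18 leukocyte markers, Tyrobp fell by 0.25 ± 0.07 and 17 did not pass, also adjusted over the list alone, with a median of -0.06 (camera adjusted p = 0.0701, and 0.0251 without knockout RAS replicate 4), and Tyrobp lost its call without any single array other than wild-type RAS replicate 4. Tyrobp lay at 4.43 in wild-type and 4.18 in knockout arrays, below the array medians. Of 4 melanocyte markers, too few for a list test, Pmel fell by 0.28 ± 0.06 and 3 did not pass, although all of these lay at a median of -0.19 and 3 fell adjusted over the list alone. Melanocyte transcripts were abundant in both genotypes, with Dct, named after its values were seen, at 10.58 ± 0.04 in wild-type and 10.40 ± 0.13 in knockout arrays (SD, n = 4 per group). Of 11 endothelial markers, Ecscr rose by 0.60 ± 0.09 and 10 did not pass, also adjusted over the list alone (camera adjusted p = 0.797), and the median of -0.06 and the mean of 0.02 differ in sign.

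**Figure D2:**
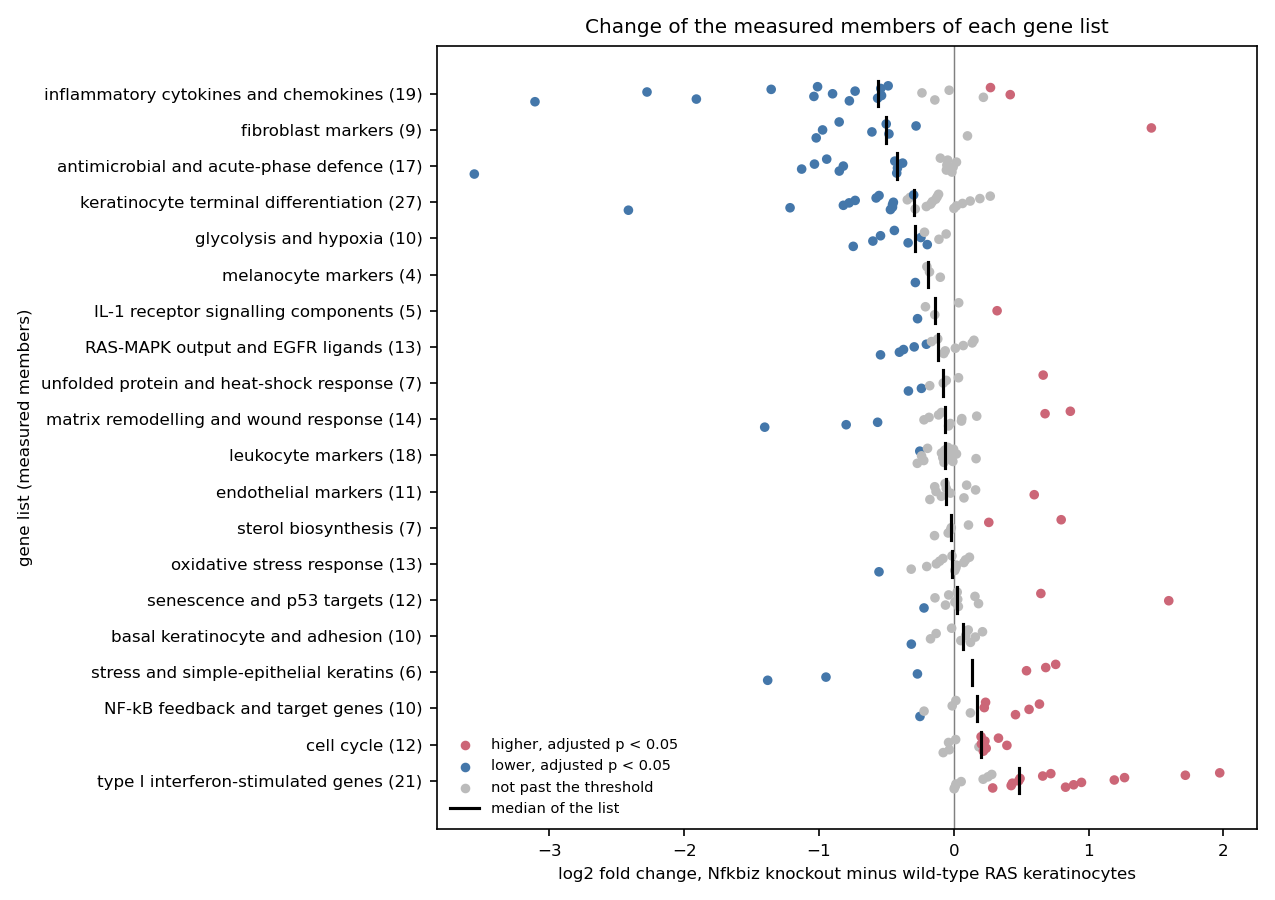
Log2 fold change, knockout minus wild-type RAS keratinocytes, of each measured member of the 20 gene lists, with the number of measured members in brackets. Points are genes, coloured by whether the adjusted p was under 0.05, and the black lines are list medians, which run from -0.56 for cytokines and chemokines to 0.48 for interferon-stimulated genes.

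Several of the largest changes lay outside the lists. Cbr2, a carbonyl reductase gene, fell from 8.92 ± 0.11 to 6.71 ± 0.07 (SD, n = 4 per group), and the transmembrane protein gene Tmem45a fell from 10.38 ± 0.12 to 8.43 ± 0.19. Mab21l3 and Lancl3 fell by 1.60 ± 0.10 and 1.59 ± 0.09 (SE), and the transcript U90926 fell by 1.42 ± 0.08. The knockout mean of Lancl3, 3.76, lay below the array medians. Among the rises, Serpinb6b, a serine protease inhibitor gene, changed by 1.69 ± 0.09, Bex1 by 1.61 ± 0.10, the epidermal lipoxygenase gene Alox12e by 1.38 ± 0.14 and Calcb, the gene of beta-CGRP, by 1.24 ± 0.10. Plscr2, a phospholipid scramblase gene, rose by 1.37 ± 0.09 but only from 2.93 to 4.30, both below the array medians.

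Genes close to Nfkbiz were examined because a knockout allele can carry flanking DNA of another strain. Of 5 tested genes within 20 neighbours on either side, 2 were called, Gm6958, which rose by 0.56 ± 0.07 (SE), and Tfg, which fell by 0.26 ± 0.05, both named after their values were seen. The share of called genes was 40.0% there against 8.88% elsewhere (Fisher's exact test, two-sided, p = 0.066). Within 50 neighbours, 4 of 19 genes were called (two-sided exact p = 0.0823), which added Filip1l, also named after its values were seen, and Tmem45a, and Tmem45a lay 22 genes from Nfkbiz in the order of the reference table. An excess of calls near Nfkbiz was thus not shown at any of these distances, and too few genes were measured there to exclude one.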

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

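In 306 groups of 4 array values (75 and 55 named genes, 20 list means, the array medians, the upper quartiles and the first principal component, each in 2 genotypes), 12 had 1 array far from the other 3, where chance gives about 15.3 (1 in 20). Bex4 and Anxa9 were named only after their values were seen. In the knockout group, Mab21l3 stood at 4.70 in replicate 4 against 5.12 to 5.19 in the others, and Cdkn2b at 8.02 against 8.19 to 8.22 and Ccn2 at 12.31 against 12.45 to 12.46 in the same replicate. Knockout replicate 1 had Anxa9 at 7.88 against 8.12 to 8.17, and its mean of the glycolysis and hypoxia list was 7.94 against 7.97 to 7.98. The mean of the melanocyte markers was 8.31 in knockout replicate 4 against 8.55 to 8.60 in the others. In the wild-type group, Relb stood at 6.97 in replicate 4 against 6.56 to 6.60, and Sdf2l1 at 9.19 against 9.23 to 9.24 in the same replicate. Replicate 2 of the wild type had Chil1 at 7.69 against 7.84 to 7.87 and Twist2 at 8.44 against 8.53, and replicate 1 had Alox12b at 5.03 against 5.23 to 5.26 and Bex4 at 3.28 against 2.87 to 2.92. All are log2 signals.

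Probe sets outside the gene comparison also carried differences between the genotypes. Among those with several symbols or none, 68 were higher and 33 lower in the knockout by limma over all probe sets. No gene is named from them.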

How the results depend on the processing

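The alternatives with genes under a log2 signal of 5, or with _x_at and _s_at probe sets, left out were chosen after seeing the data. No named gene or list that passed changed direction in any alternative run, and none passed in the opposite direction. Medians of lists that did not pass could change sign, as that of the sterol list did. It turned from -0.018 to 0.0084 with arrays centred on their median. The count of 827 genes stayed within 1.5 times under each other table or fit, between 598 without wild-type replicate 2 and 1134 with trend and robust settings. It was 177 with a 1.5-fold minimum, 430 at an adjusted p of 0.01 and 187 with treat against 1.2-fold, which are stricter by construction. With the replicate block, 659 genes passed, 629 of them shared. Over all genes, same-numbered arrays did not deviate together (correlations 0.09, 0.00, 0.03 and -0.05), and 2 of 8 arrays matched their own number best. Replicate 1 had the lowest mean of the differentiation list in both genotypes (8.80 in wild-type and 8.31 in knockout arrays). The lowest mean of the antimicrobial list was in wild-type replicate 2 and knockout replicate 1. Pairing by number was thus not shown, and it was not excluded. Of the 19 lists, 9 passed with the preset correlation, 4 with an estimated correlation and 14 with fry. With an estimated correlation, the adjusted p was 0.254 for the NF-kB, RAS-MAPK and differentiation lists, 0.178 for cell cycle and 0.1345 for fibroblast markers, which allows for co-varying members. With fry, which does not compare a list with other genes, it was 0.0338 for stress keratins, 0.000649 for senescence, 0.00168 for matrix, 0.0282 for sterol and 0.00929 for leukocyte markers. The NF-kB list reached 0.0511 without low-signal genes, and leukocyte markers 0.0488 with the replicate block, and the cause was not tested. Leaving out each array in turn gave 0.0302 to 0.171 for senescence and 0.0251 to 0.165 for leukocyte markers. Of 117 called named genes, 91 kept the call under each other table or fit that held them, and 61 passed the 1.5-fold minimum, 86 the adjusted p of 0.01 and 65 treat. The 26 that lost the call under at least 1 other table or fit reached an adjusted p of 0.1203 at most. These were Anxa9, Arg1, Bex4, Col17a1, Defb3, Dusp5, Efemp1, Egr1, Filip1l, Hoxa10, Ikbke, Il1f8, Krt16, Lce1g, Lce1h, Lce1i, Padi1, Plk1, Plk3, Rela, Sdf2l1, Serpinb7, Sigirr, Tm7sf2, Tnip1 and Tyrobp. Scaling moved the median of all genes by at most 0.027. The alternatives for Nfkbiz and for the pseudocount were not run. Without detection calls, signals near 3 (Lcn2 in the knockout) cannot be told from background.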

Other observations

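The gene families below, and the tests of leukocyte markers, interferon ligand genes and Postn, were chosen only after the results were seen, and the other tests of this part were set before their own result was seen. A family that holds genes already seen to change, such as Serpinb6b or Bex1, was likely to give a small p-value with fry. The fry values of families are therefore descriptive, and adjusting over families does not correct for this choice. Apart from Serpinb6b, Bex1, Postn, Mmp3, Krt1 and Krt10, the genes of this part were also named only after their values were seen. Gjb2 and Gjb6, genes of gap junction connexins, fell by 1.17 ± 0.14 and 1.07 ± 0.15 (SE). Of the stefin and cystatin A genes 3 were measured and fell, Stfa3 by 1.18, Stfa2l1 by 1.09 and Csta1 by 1.02 (fry adjusted p = 0.000876 over 14 families), and such copies can share probe targets. All 4 measured Lce3 genes and all 5 measured Sprr2 genes fell, with medians of -0.91 and -1.26 (fry adjusted p = 0.000876 and 0.000252), although 4 of the Sprr2 genes passed with arrays centred on their median. None of the 3 Sprr1 and Sprr3 genes passed in limma (median -0.20, fry adjusted p = 0.03). Of 9 Lce1 genes, Lce1g, Lce1h and Lce1i fell (fry adjusted p = 0.205), and of 19 beta-defensins Defb3, Defb4 and Defb6 fell (fry adjusted p = 0.00105), with Defb3 at 3.39 in the knockout, near the arrays' lower quartiles. The knockout means of Defb4 and Lce1g, 4.227 and 4.215, lay below the array medians.

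Directions given with fry below are of the family as a whole. Of 12 Serpinb genes, Serpinb6b, Serpinb9b and Serpinb7 rose and Serpinb6c fell (fry, higher, adjusted p = 0.000875), and of 5 Bex genes Bex1, Bex3 and Bex4 rose (fry, higher, adjusted p = 0.000252), with Bex4 near 3 on the log2 scale. Serpinb7 lay at 3.88 in wild-type and 4.46 in knockout arrays, below the array medians, and its groups overlapped. Of 6 interferon-inducible GTPase genes, Gbp3, Irgm1, Irgm2 and Igtp rose by 0.89, 0.71, 0.48 and 0.46 (fry, higher, adjusted p = 0.000195). Of 172 solute carrier genes 6 rose and 11 fell (fry, lower, adjusted p = 0.0276), but their median of -0.00711 turned to 0.0036 with quantile normalization and 0.0196 with arrays centred on their median, where 10 and 8 fell. Of 22 Hox genes Hoxa10 and Hoxb6 fell by 0.34 and 0.36 (fry, lower, adjusted p = 0.023), 1 of them under either other scaling, and Hoxa10 lay at 3.26 in the knockout, where signal could not be told from background. By limma none of 23 toll-like and NOD-like receptor genes, 13 MHC genes or 33 hair keratin-associated genes passed, and fry gave adjusted p of 0.00737 (lower), 0.441 and 0.441, although 1 keratin-associated gene was higher under either other scaling. Most genes of each of these families lay below a log2 signal of 5, where a change can be hidden in background. The lack of calls therefore does not show that these families were unchanged.

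The 827 called genes were set against the other splits of the 8 arrays into 4 and 4. Only 1 of the 35 splits, the real one, called as many, and limma called 0 genes in each of the others, with at most 702 at an unadjusted p under 0.05 against 1932 in the real split. Chance is thus an unlikely source of this count, and 1 of 35 is the smallest share that this test can give. The other splits mix the genotypes, so a genotype difference widens their spread and lowers their calls. Differences between cultures that go with genotype are not addressed by this test.

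The rise of interferon-stimulated genes in the knockout, median 0.48, was weighed first. Leukocytes among the knockout cells would raise leukocyte markers, but these had a median of -0.0633 (95% bootstrap interval over 18 genes -0.138 to -0.0271), the most abundant being Cd68 at 6.41. Only 5 of the 18 had signals of 5 or more, with a median of -0.0013 (interval -0.239 to 0.166) and none called by limma, so a leukocyte share too small to lift the others above background stays open. A broad response beyond the list stays open: a further list of 23 interferon genes had a median of 0.135 (interval 0.0166 to 0.295), with 9 higher and Xdh lower. More interferon transcript also stays open, since 8 type I interferon genes had a median of -0.0308 at mean signals of 2.59 to 5.06, too low to decide.

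The fall of fibroblast markers, median -0.50, may come from fewer fibroblasts in the knockout cultures or from expression. A further list of 17 fibroblast genes had a median of -0.118 (interval -0.168 to 0.0972), short of the fall that fewer fibroblasts as the whole cause would give. Members with log2 signals little above 5 can hide a fall in background, so this list cannot decide. Its 4 genes with signals above 8, such as Pdpn at 10.4, may be expressed by keratinocytes and hide a small share, and Olfml3, Rcn3 and Srpx2 fell while Efemp1 rose, a call lost without wild-type replicate 4 or knockout replicate 2, 3 or 4. Postn rose by 1.466 (95% interval 1.27 to 1.67), which a smaller share forbids for that gene. A loss of fibroblasts, and its part in the fall of Mmp3, stays open.

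The fall of cornified envelope, Sprr2 and Lce3 genes may reflect a general loss of terminal differentiation. A further list of 45 cornification genes without Sprr or Lce members had a median of -0.2478 (interval -0.352 to -0.162), as such a loss predicts. Of these genes, 21 were lower and Padi1, Anxa9 and Arg1 were higher. The interval treats genes as independent. None of the 45 passed as higher without wild-type replicate 1 or 4 or knockout replicate 2, 3 or 4. The number lower ranged from 17 without wild-type replicate 2 or 3 to 23 without wild-type replicate 1. Variation between cultures of either genotype stays open. The means of the fixed differentiation list were 8.31 to 8.64 in the knockout and 8.80 to 9.02 in the wild type (two-sided exact permutation p = 0.02857, the smallest that 4 against 4 can give), but the list was taken up because it fell, so this separation was to be expected, and allowing for members that vary together gave an adjusted p = 0.254 by camera and 0.00625 by fry. Krt1 and Krt10 did not pass the test, and early against late genes were not compared.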
